A study of Homo sapiens with 6 samples.

How the data were processed

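Total RNA of HCT-116 cells was isolated with Trizol, treated with DNase, and 4 µg per sample was labelled by reverse transcription with biotinylated random octamer primers, per the labels' protocols. Each of the 6 one-colour arrays carried 1 sample. The deposited table holds 2997 probes by 6 arrays. Per the values in the deposited table, the signals are log2 values already normalized by the authors: array medians lay between 6.56 and 6.60, and the highest value on each array lay just under 16, the log2 ceiling of a scanner, which is where the base of the logarithm is taken from. The submitters' processing notes name limma, with no version. The background correction, the normalization method and the genome build are not given in the sources used here, so no coordinates are printed.

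Probes were sorted by name. Of the 2997 probes, 1741 were human miRNA probes and 32 were named for transcripts of ultraconserved regions, and these 1773 probes were tested. Among the human miRNA probes, 1115 were read as mature-named and 626, with the suffix P or AP or a like tag, as precursor-named. The suffix is not explained in the sources used here, so "precursor-named" describes the name only. The 1084 mouse-named probes, 93 mismatch probes, 38 random-sequence probes, 4 small nucleolar RNA probes, 2 GAPDH probes and 3 blank or spacer probes stayed out of the main tests. Of 844 distinct human miRNA names, 774 matched a miRNA gene name in the RefSeq gene table of the human reference assembly GRCh38.p14 and 70 did not. Names follow the array, including its older names and its spelling "has" in some of them. All 6 columns were matched to a sample by its identifier, and no probe was removed for low signal in the main tests.

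The groups were mock (empty vector), variant 1 and variant 2 of Uc283+a, with 2 arrays each. Replicate numbers follow the order of deposit and pair nothing. With 2 arrays per group, the number of arrays limits the precision. A limma model (version 3.58.1, R 4.3.3) was fitted to all 6 arrays with 1 mean per group, which left 3 residual degrees of freedom per probe, to which the empirical Bayes prior added 5.71. The comparisons were the mean of both variants against mock, each variant against mock, and variant 2 against variant 1. P-values were adjusted by the Benjamini-Hochberg method over the 1773 probes, with a threshold of 0.05. All tests were two-sided. Intervals of single probes are 95% intervals of the limma fit, and those of a mean over several probes come from a linear model of the array means with 3 residual degrees of freedom.

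Before the data were examined, 23 miRNA lists were fixed: the seed family of miR-15, miR-16 and miR-195, the clusters of miR-17, miR-92a and their paralogs, the let-7, miR-200, miR-29 and miR-30 families, the intestinal epithelial miR-192, miR-194 and miR-215, p53-induced miRNAs, colorectal oncomiRs, colorectal tumour-suppressor miRNAs, miRNAs of genes methylated in colorectal cancer, miRNAs made without Drosha or DGCR8, miRNAs whose Microprocessor cropping is regulated by p53, SMAD proteins or KSRP, innate immune and NF-kB miRNAs, hypoxia and stress miRNAs, the imprinted 14q32 cluster, the placental C19MC cluster, the embryonic miR-302 and miR-371 clusters, and markers of haematopoietic cells, muscle, neural tissue, liver and fibroblasts. A list took the mature-named and precursor-named probes of its members. Several lists share members, so their tests are not independent. Lists were tested with camera at its preset correlation of 0.01, adjusted over the 23 lists. Camera with an estimated correlation and fry were run beside it. The precursor-named, mature-named and ultraconserved-region probes were tested as 3 classes in the same way.

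The named probes were also chosen by a rule fixed before the data were examined. It takes every probe of the miR-195 seed family, the 10 higher and 10 lower probes with the largest change past the threshold for both variants against mock, 4 of each for the other comparisons, and for each list the 2 members with the smallest p. Where too few probes passed, the places went to the smallest unadjusted p among probes whose arrays did not overlap between the groups, and the text says that these did not pass. A probe is called above background where it exceeded, on all 6 arrays, the 95th percentile of the 38 random-sequence probes of that array. This definition was chosen after the data were seen and removed nothing from the main tests. Any other probe is called below background. By it, 389 tested probes were above background, 259 of them mature-named, 128 precursor-named and 2 for ultraconserved regions.

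The limma and camera steps were tested on simulated data with the real probe means, variances drawn from the fitted prior, and 200 of 1773 probes changed by known amounts, 50 of each size. For both variants against mock, the model recovered 8.9% of 2-fold changes, 46.8% of log2 changes of 1.5, 81.3% of 4-fold changes and 96.2% of 8-fold changes, with 4.58% false among its calls. For variant 1 against mock, these shares were 6.2%, 24.1%, 62.8% and 94.3%, with 5.11% false. These shares hold for 200 changed probes and for arrays of equal spread. With fewer changed probes the adjusted threshold is harder to reach, and deviating arrays were not simulated. The shares may therefore be too high for the real arrays, and 0 calls do not exclude 4-fold changes of few probes. A list of 15 probes was scored alone, at an unadjusted camera p under 0.05, with probes simulated as independent. Shifted by 0.3 in log2, it reached this in 60% of 20 simulations of either comparison. Shifted by 0.5, it did so in 100% for both variants and 95% for variant 1. With no shift it passed in 0% and 10%.

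The alternatives were quantile normalization, median centring and cyclic loess between arrays, filters on dim probes, trended and robust priors, array weights, 1 value per miRNA name, all probes or mature-named probes alone, fits of only the groups compared, the other list tests, and leaving out each array in turn. Tests on probes above background alone were added after the data were seen.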

Results

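HCT-116, a human colorectal carcinoma cell line, was transiently transfected with an empty vector (mock) or with 1 of 2 forms of the long noncoding RNA Uc283+a, and small-RNA probes were read on microarrays. The RNA is transcribed from an ultraconserved region, a stretch of sequence kept identical between distant mammals. Variant 1 carries a run of 8 T in its sequence and variant 2 a run of 9 T. The design asks which miRNAs respond to Uc283+a, and the study concerns the processing of primary miRNA transcripts. Each group had 2 arrays. No label says that these came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

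Values are log2 signals normalized by the authors. The number of tested probes above the random-sequence level was 647 and 673 on the mock arrays, 703 and 585 on the variant 1 arrays, and 452 and 757 on the variant 2 arrays. Probes for hsa-miR-1273c, hsa-miR-543-P and mmu-miR-290-5p stood at the scanner ceiling on all 6 arrays and carry no measurable change. Across all probes, arrays of the same group correlated at r = 0.909 to 0.917 and arrays of different groups at 0.900 to 0.921, so the groups were no tighter than the whole set. Among probes above background, the SD of the log2 difference between the 2 arrays of a group was 0.755 for mock, 0.667 for variant 2 and 0.463 for variant 1. Mock replicate 1 and variant 2 replicate 2 stood apart, with SDs of 0.667 to 0.837 against the other arrays, where the remaining pairs lay between 0.463 and 0.576. No tested probe names Uc283 itself, so the level of the transfected RNA was not analysed here.

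The miRNA that the study follows, miR-195, gave 9.29 ± 0.085 (SD, n = 2) in mock, 8.50 ± 0.116 (n = 2) with variant 1 and 8.72 ± 0.372 (n = 2) with variant 2 for its mature-named probe hsa-miR-195. This miRNA belongs to the miR-15/16 seed family, whose members repress cyclins and other drivers of the cell cycle. Its difference from mock was -0.68 (SE 0.333, 95% interval -1.44 to 0.08) for both variants together, -0.79 (SE 0.385) for variant 1 and -0.57 (SE 0.385) for variant 2, with all 4 variant arrays below both mock arrays. The difference between variants was 0.22 (SE 0.385). The opposite strand, hsa-miR-195*, was below background, with a difference of -0.65 (SE 0.650). In limma, hsa-miR-195 reached an unadjusted p of 0.0722 and an adjusted p of 0.975 for both variants, and the adjusted p over the list alone was 0.760, so it did not pass. The 4 small nucleolar RNA probes, kept out of the tests, had a mean change of -0.55 on the same arrays (95% interval -1.26 to 0.17). A fall of this size was therefore not particular to miR-195. No human precursor-named probe of miR-195 was analysed here, so mature and precursor signals could not be set side by side for this miRNA. Total RNA was labelled with random primers, so a mature-named probe may also read precursor RNA that holds the same sequence.

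The family, miR-195 included, did not pass as a set, and its other members were not tested apart from miR-195. For both variants, hsa-miR-497, which is made from the same primary transcript as miR-195, differed from mock by 0.29 (SE 0.352), hsa-miR-16 by -0.24, hsa-miR-15a by 0.01, hsa-miR-15b by -0.42 and hsa-miR-503 by -0.53. Among strands and precursors, hsa-miR-16-2* differed by -0.76, hsa-miR-15b* by -0.38, hsa-miR-497* by -0.20, hsa-miR-16-1* by -0.12, hsa-miR-15a* by -0.03, and hsa-mir-503-P by 0.25. The probes hsa-miR-424 and hsa-miR-424* were 0.37 and 0.34 above mock. In all, 10 of the 15 family probes were lower and 5 higher, with a median of -0.20, and only 4 of the 15 lay above background. Camera gave the family an adjusted p of 0.412 for both variants, 0.491 for variant 1, 0.627 for variant 2 and 0.873 for the difference between variants. Without mock replicate 1, hsa-miR-16 differed from mock by 0.65 and hsa-miR-15a by -0.39.

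**Figure D1:**
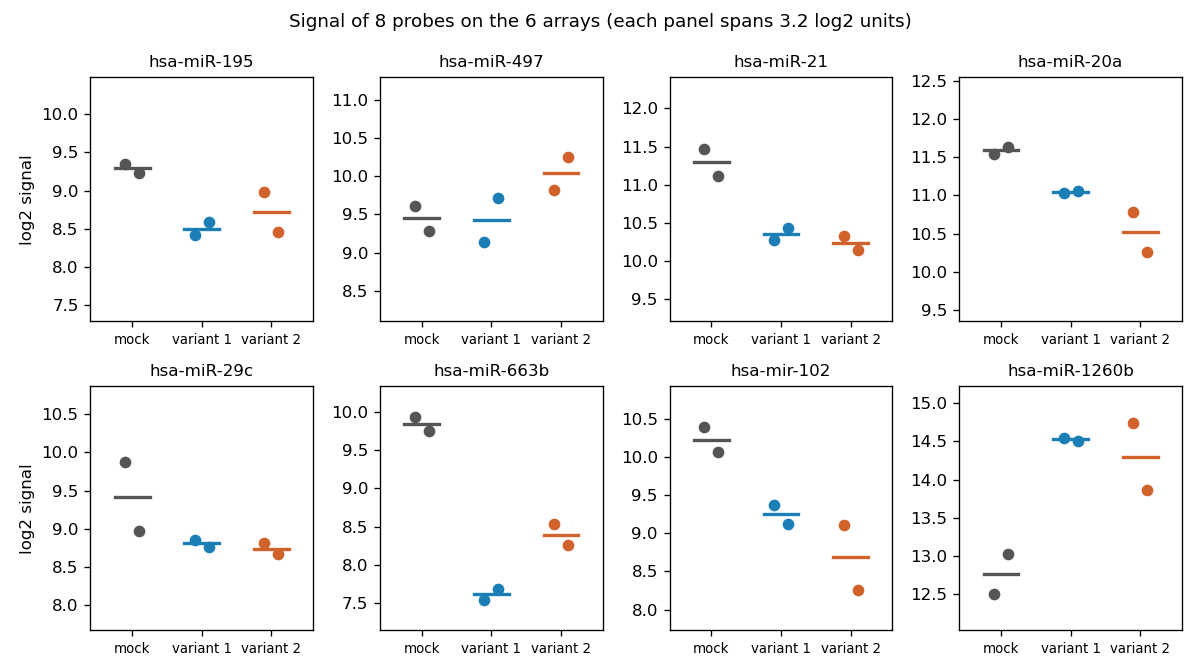
Log2 signal of 8 probes on the 6 arrays; points are single arrays, short lines are the means of the 2 arrays of a group, and each panel spans the same range of log2 units. The variant arrays of hsa-miR-195, hsa-miR-21, hsa-miR-20a, hsa-miR-663b and hsa-mir-102 all lie below both mock arrays and those of hsa-miR-1260b above, and none of these differences passed the test over all probes.

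With both variants set against mock, the lowest probe was hsa-miR-663b, at 9.84 ± 0.132 (SD, n = 2) in mock and 8.00 ± 0.469 (n = 4) in the variants, a difference of -1.84 (SE 0.321). The abundant oncogenic miRNA hsa-miR-21 stood at 11.29 ± 0.250 in mock and 10.29 ± 0.118 in the variants, a difference of -1.0 (SE 0.324). The probe hsa-mir-102 differed by -1.26 (SE 0.368), also above background. Its name is an older one with no match in the RefSeq gene table, so which current miRNA it reads was not settled here. The brightest of the higher probes chosen by the rule was hsa-miR-1260b, a sequence that overlaps a transfer RNA, at 12.77 ± 0.368 in mock and 14.41 ± 0.384 in the variants, a difference of 1.65 (SE 0.378). None of these passed: the smallest adjusted p in limma was 0.564, for hsa-miR-663b. On the same arrays the small nucleolar RNA probes changed by -0.31 to -0.74.

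Further higher probes chosen by the rule were hsa-miR-1200-P (1.06, above background) and, below background, hsa-miR-889-P (1.66), hsa-miR-122* (1.60), hsa-mir-630-P (1.38), hsa-miR-1283 (1.18), hsa-mir-596-P (1.09), hsa-mir-1912 (1.09), hsa-miR-133a-1-P (1.09) and hsa-mir-579-P (1.04). Further lower probes, all below background, were hsa-miR-1972 (-1.50), hsa-miR-1827 (-1.47), hsa-mir-633-P (-1.34), hsa-miR-3175 (-1.18), hsa-miR-92a-1* (-1.17), has-miR-7-1* (-1.11) and hsa-miR-516a-3p (-1.0). None of the 20 passed, and the log2 signals of the probes below background give no measured fold. Limma called 0 of 1773 probes, with 39 higher and 43 lower at an unadjusted p under 0.05, where chance gives 88.65. With a trended prior limma called 1 probe, hsa-miR-1260b, at an adjusted p of 0.0469. The arrays of mock and of the variants did not overlap for 13.25% of probes, where chance gives 13.33%.

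Among the fixed lists, the miR-29 family, whose members target collagens and DNA methyltransferases, fell as a set for both variants against mock. All 7 of its probes were lower, 4 of them above background, with a median of -0.46 and a mean of -0.53. The brightest, hsa-miR-29a (10.35 in mock), named outside the rule, differed by -0.28. Camera gave the family an adjusted p of 0.0264, against 0.538 with an estimated correlation. The 4 small nucleolar RNA probes, kept out of the tests, were lower on the same arrays by a like amount, with a mean change of -0.55 and single changes of -0.31 to -0.74. In this family hsa-miR-29b-1* differed by -0.93 (SE 0.377), from 8.31 ± 0.661 to 7.38 ± 0.171, and hsa-miR-29c by -0.65 (SE 0.365), from 9.42 ± 0.635 to 8.77 ± 0.079, neither past the threshold alone. Without mock replicate 1 these differences were -0.46 and -0.20, and without mock replicate 2 they were -1.40 and -1.10. Fry gave the family an adjusted p of 0.152. The family's median was -0.34 without mock replicate 1 (adjusted p 0.229), -0.32 without variant 1 replicate 1 (0.106), -0.61 without variant 1 replicate 2 (0.0604) and -0.41 without variant 2 replicate 2 (0.203), so the call was lost in each of these 4 fits. Over the settings that kept all arrays its adjusted p ran from 0.0193 to 0.538.

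The let-7 family, repressors of RAS and MYC, had a median of -0.28 with 16 of 22 probes lower, among them hsa-let-7d-v2-P (-0.85) and hsa-let-7a2-p (-0.68). Camera gave it an adjusted p of 0.0721. The miRNAs whose Microprocessor cropping is regulated by p53, SMAD proteins or KSRP had a median of -0.18 with 29 of 37 lower and an adjusted p of 0.0721. This list holds hsa-miR-21 and hsa-miR-20a (-0.81, SE 0.331). The innate immune and NF-kB list, which also holds hsa-miR-21 and hsa-miR-29b-1*, had a median of -0.23 with 18 of 25 lower. Its adjusted p was 0.134 with camera and 0.0426 with fry, which tests the list by itself rather than against other probes. The clusters of miR-17, miR-92a and their paralogs, which drive proliferation, had a median of -0.13 with 18 of 27 lower (adjusted p 0.146), with hsa-miR-92a-1* and hsa-miR-20a having the smallest p. The miR-30 family had a median of -0.21 with 9 of 11 lower (adjusted p 0.146), including hsa-miR-30c (-0.84, SE 0.332) and hsa-miR-30b* (-0.47).

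The epithelial miR-200 family had a median of -0.11 with 7 of 10 probes lower (camera adjusted p 0.412), among them hsa-miR-141 (-0.96) and hsa-miR-200a (-0.95), both below background. The intestinal list of miR-192, miR-194 and miR-215, with 0 of 7 probes above background, had a median of 0.11 (adjusted p 0.918), with hsa-miR-194 at -0.78 and hsa-mir-215-P at 0.56. The p53-induced miRNAs had a median of -0.10 and a mean of 0.01 of opposite sign, with camera's direction up (adjusted p 0.998), and included hsa-miR-1246-P (0.56) and hsa-miR-34b* (0.32). Colorectal oncomiRs had a median of -0.08 (adjusted p 0.728), with hsa-miR-21 lower and hsa-miR-96* at 0.71. Colorectal tumour-suppressor miRNAs, which include hsa-miR-195 and hsa-miR-133a-1-P, had a median of -0.01 against a mean of 0.06 and an upward test (adjusted p 0.714). The miRNAs of genes methylated in colorectal cancer had a median of 0.14 (adjusted p 0.412), with hsa-miR-127-3p at 0.76 and hsa-miR-129* at -0.82. The miRNAs made without Drosha or DGCR8, 26 of whose 35 probes were above background, had a median of 0.10 (adjusted p 0.820), with hsa-miR-320c at -0.86 and hsa-mir-484-P at 0.68. Hypoxia and stress miRNAs had a median of -0.12 (adjusted p 0.331), with hsa-miR-193b at -0.67 and hsa-miR-27a at -0.63.

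Markers of other cell types showed no list past the threshold. Haematopoietic markers had a median of 0.18 with 11 of 15 probes higher (camera adjusted p 0.146), among them hsa-miR-144 (0.94) and hsa-miR-223* (0.71), both below background. Muscle markers had a median of 0.13 (adjusted p 0.412), with hsa-miR-133a-1-P higher and hsa-mir-208b at -0.85. Neural markers had a median of -0.04 and a mean of 0.01 with an upward test (adjusted p 0.987), with hsa-miR-338-3p at 0.62 and hsa-miR-9* at -0.44. The liver list held only hsa-miR-122 (-0.10, above background) and hsa-miR-122* (adjusted p 0.329 for the list). Fibroblast markers had a median of -0.10 (adjusted p 0.412), with hsa-miR-199b-3p at -0.58 and hsa-miR-199a-3p at -0.52. The imprinted 14q32 cluster had a median of -0.01 and a mean of 0.01 with an upward test (adjusted p 0.983), including hsa-miR-889-P. The placental C19MC cluster, with 1 of 73 probes above background, had a median of 0.03 (adjusted p 0.714), including hsa-miR-1283 and hsa-miR-524-3p (0.94). The embryonic miR-302 and miR-371 clusters had a median of 0.08 (adjusted p 0.412), with hsa-miR-367 at 1.16 and hsa-miR-302d* at 0.99. Over the 23 lists, 7 had an unadjusted camera p under 0.05, 1 passed after adjustment, 0 passed with an estimated correlation and 1 passed with fry. No member passed over all probes, and adjusted over the list alone 1 passed, hsa-miR-122* in the liver list of 2 probes. It was below background, and its difference was 2.56 without mock replicate 1 and 0.64 without mock replicate 2.

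**Figure D2:**
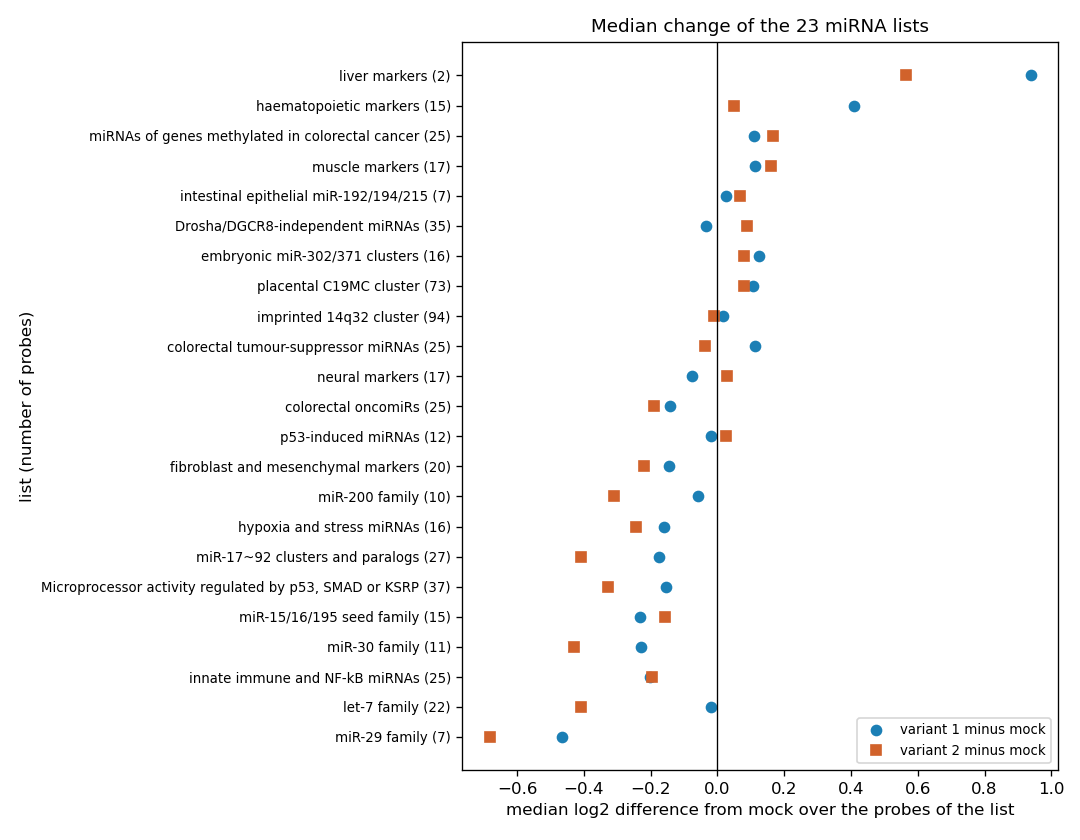
Median log2 difference from mock of each of the 23 miRNA lists for variant 1 (circles) and variant 2 (squares), with the number of probes of each list in brackets and a line at 0. The miR-29 family has the lowest median for each variant (-0.47 and -0.68), and the let-7 family stands at -0.02 for variant 1 and -0.41 for variant 2.

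With variant 1 set against mock, the lowest of the named probes was again hsa-miR-663b, with 7.61 ± 0.096 (SD, n = 2) against 9.84 ± 0.132 (n = 2) in mock, a difference of -2.23 (SE 0.371). Higher probes were hsa-miR-1260b (1.76, SE 0.436) and, below background, hsa-miR-889-P (1.78), hsa-miR-548a-5p (1.62) and hsa-mir-630-P (1.52). Other lower probes, below background, were hsa-miR-1265-P (-1.71), hsa-miR-3175 (-1.44) and hsa-miR-92a-1* (-1.43). None passed in limma, where the smallest adjusted p was 0.398, for hsa-miR-663b. Limma called 0 probes, with 34 higher and 39 lower at an unadjusted p under 0.05 and 88.65 given by chance. The arrays did not overlap for 33.8% of probes, where chance gives 33.3%.

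The miR-29 family had a median of -0.47 with 7 of 7 probes lower for variant 1, and the haematopoietic markers a median of 0.41 with 12 of 15 higher, each at a camera adjusted p of 0.253. Camera called 0 of the 23 lists, with 2 at an unadjusted p under 0.05, and 0 with an estimated correlation. Fry called 2 lists, the miRNAs of genes methylated in colorectal cancer (median 0.11, 15 of 25 higher) and the innate immune and NF-kB miRNAs (median -0.20, 15 of 25 lower), each at an adjusted p of 0.0461. Adjusted over the list alone, 1 member passed, hsa-miR-122*, again below background.

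With variant 2 set against mock, the higher probes were hsa-miR-1260b (1.53, SE 0.436) and hsa-miR-1979 (1.39, SE 0.432), a Y RNA-related sequence, both above background, with hsa-miR-889-P (1.54) and hsa-mir-579-P (1.41) below it. Lower probes were hsa-miR-663b (-1.45, SE 0.371) and, below background, hsa-miR-2276-P (-1.97), a probe for an ultraconserved-region transcript (-1.87) and hsa-miR-4271 (-1.61). None passed in limma, and the smallest adjusted p was 0.938, for hsa-miR-2276-P. Limma called 0 probes, with 40 higher and 45 lower at an unadjusted p under 0.05 and 88.65 given by chance. The arrays did not overlap for 33.3% of probes, the share that chance gives.

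With variant 2, 5 lists fell in camera at its preset correlation, and none of the 5 calls held with an estimated correlation (adjusted p 0.406 for 4 of them and 0.527 for the clusters of miR-17 and miR-92a) or with fry. The let-7 family had a median of -0.41 with 18 of 22 probes lower (adjusted p 0.00221). The miR-29 family had a median of -0.68 with 7 of 7 lower (adjusted p 0.00997). The Microprocessor-regulated miRNAs had a median of -0.33 with 30 of 37 lower (adjusted p 0.00997). The clusters of miR-17 and miR-92a had a median of -0.41 with 17 of 27 lower (adjusted p 0.0455). The innate immune and NF-kB list had a median of -0.19 with 17 of 25 lower (adjusted p 0.0478). No member passed over all probes or adjusted over the list alone. The 4 small nucleolar RNA probes, kept out of the tests, were also lower with variant 2 than in mock, with changes of -0.42 to -0.74. Without variant 2 replicate 2, 1 of the 2 arrays that stood apart, camera called 0 of the 23 lists, the let-7 median being -0.30 (adjusted p 0.245) and the miR-29 median -0.61 (0.245). Without mock replicate 1, the other array that stood apart, it called 1 list, and the miR-29 median was -0.40 (adjusted p 0.178).

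The comparison of variant 2 with variant 1 sets the 2 lengths of the T run side by side. The level of the transfected RNA was not analysed, so an effect of length cannot be told from one of level or from differences between the arrays. Higher in variant 2 were hsa-miR-593* (1.49, SE 0.391, above background) and, below background, hsa-miR-199b-5p (2.09), hsa-miR-1289-1-P (1.69) and hsa-miR-296-3p (1.47). Lower were hsa-miR-548a-5p (-1.87), hsa-miR-2276-P (-1.77), hsa-miR-500 (-1.41) and hsa-mir-649-P (-1.39), all below background. None passed in limma, and the smallest adjusted p was 0.924, for hsa-miR-548a-5p. Limma called 0 probes, with 43 higher and 45 lower at an unadjusted p under 0.05 and 88.65 given by chance. The arrays did not overlap for 35.5% of probes, where chance gives 33.3%.

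The let-7 family was lower with variant 2 than with variant 1, with a median of -0.45 and 19 of 22 probes lower. Camera gave an adjusted p of 0.0167, against 0.894 with an estimated correlation, and fry gave 0.392. Values of members, chosen after they were seen, were -0.65 for hsa-let-7a, -0.67 for hsa-let-7c, -0.66 for hsa-let-7d and -0.16 for hsa-let-7e, none past the threshold. The call was lost without variant 1 replicate 1 (median -0.49, adjusted p 0.641), without variant 2 replicate 2 (median -0.30, adjusted p 0.820) and with mature-named probes alone (median -0.36, adjusted p 0.0640). Over the settings that kept all arrays its adjusted p ran from 0.000925 to 0.894. Camera called 1 of the 23 lists here, with 2 at an unadjusted p under 0.05, and 0 lists passed with an estimated correlation or with fry.

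Precursor-named and mature-named probes did not separate. For both variants against mock the median change was 0.01 over 626 precursor-named probes and -0.03 over 1115 mature-named probes, with a camera adjusted p of 0.660 for each. Over 574 miRNAs with both kinds of probe, the median of the mature minus the precursor change was 0.006 for both variants, 0.037 for variant 1, 0.040 for variant 2 and -0.014 between variants, against an SD across miRNAs of 0.635 to 0.751. For both variants, the mature and precursor changes correlated across these miRNAs at r = 0.009. With mostly dim probes, and mature-named probes that may also read precursor RNA, these medians do not settle whether processing changed. The 32 ultraconserved-region probes, 2 of them above background, had a median of -0.08 and a mean of 0.0009, with camera's direction down (adjusted p 0.706). Between variants their median was -0.30, with a camera adjusted p of 0.0854, against 0.622 with an estimated correlation. None of the 3 classes passed in any comparison.

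The changes of the 2 variants from mock correlated across probes at r = 0.469 (Spearman 0.449), where probes are not independent replicates. Simulated unchanged groups that shared 2 simulated mock arrays gave a mean r of 0.504, from 0.430 to 0.582 over 100 simulations. The covariance was 0.129 against 0.140 in the simulations, and 65.7% of probes had the same sign against 66.8%. At an unadjusted p under 0.05, 12 probes were higher in both variants and 8 lower in both, where independent lists give 0.767 and 0.990. They included hsa-miR-1260b, hsa-miR-663b, hsa-mir-102 and hsa-miR-21. The 2 mock arrays cannot be split into parts of 2, so some or all of this overlap may come from the shared mock arrays.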

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

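The camera tests and the fits that leave out 1 array were planned, and the tests with random lists, resampled probes and mouse-named probes were chosen after the let-7 difference had been seen. The median difference of the 22 let-7 probes between variant 2 and variant 1 was -0.45, singled out because a test of the difference between the variants itself passed in camera at its preset correlation (adjusted p 0.0167), but not with an estimated correlation (adjusted p 0.894). A trend with brightness between arrays is argued against: over 10000 random lists of 22 probes of like brightness the median was -0.006. Of these lists, 0.01% had a median as low as that of let-7. Since let-7 was singled out for its difference in these same data, that share is no separate support. One deviating array stays a possible explanation: without variant 2 replicate 2 the median was -0.30, with a range over resampled probes of -0.46 to -0.02. Differences between single probe designs also stay open, since 9 mouse-named let-7 probes above background had a mean difference of -0.37 (95% interval -0.99 to 0.25), in the direction of the 11 human ones (-0.54, -1.35 to 0.28). An effect of the length of the T run, the biological difference that the design names, is likewise open and untested beyond this comparison of 2 arrays with 2.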

How the results depend on the processing

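Tests on probes above background alone and those of the fragment list were added after the data were seen; where a call or sign changed, the cause was not tested. The probe calls stayed at 0 in all comparisons under every alternative, except 1 with a trended prior for both variants (hsa-miR-1260b, change 1.65, adjusted p 0.0469, with 0.0469 to 0.987 over the alternatives). Signs were followed over the alternatives for 65 results of single probes, which did not take in every named list member. None of these signs turned unless an array was left out. For both variants, hsa-miR-195 stayed between -0.69 and -0.66 over the alternatives (lowest adjusted p in limma 0.618). Its range was -0.81 to -0.55 when arrays were left out. The fragment median stayed between 0.49 and 0.71, or 0.47 and 0.86 without 1 array. For both variants against mock, 1 list passed in the main test, 0 with an estimated correlation or cyclic loess (miR-29 adjusted p 0.0619 there), 2 above the 25th percentile of brightness or its median (let-7 then also passing), 5 among probes above background, and 0 to 5 when an array was left out. For variant 1, fry called 2. For variant 2, the 5 lists became 0 with an estimated correlation or fry, 3 above the median brightness or with mature-named probes alone, and 0 to 5 without 1 array. Between variants, the 1 list became 0 with an estimated correlation, fry or mature-named probes alone, 2 above the median or among probes above background, and 0 to 1 without 1 array.

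Shifts near 0 turned sign. For ultraconserved-region probes relative to all others, both variants, 0.0041 became -0.0040 with quantile normalization, -0.0081 with cyclic loess, -0.017 and -0.097 above the 25th percentile and the median, -0.36 among probes above background (2 probes), and -0.099 to 0.11 without 1 array; for variant 1 it was -0.094 among probes above background. Between variants it was -0.35 to -0.16 without 1 array, passing at -0.35 without variant 2 replicate 1 (adjusted p 0.0427). The precursor-named shift for variant 1 was -0.026 among probes above background and -0.0037 to 0.050 without 1 array, and between variants -0.018 to 0.073. The let-7 median for variant 1 was 0.042 among probes above background and -0.23 to 0.10 without 1 array. Without 1 array, the miR-195 seed family median ran from -0.24 to 0.025 for variant 2 and -0.12 to 0.41 between variants, and the miR-29 median between variants from -0.14 to 0.0013. For both variants, without 1 array, hsa-miR-15a ran from -0.39 to 0.41, hsa-miR-15a* from -0.47 to 0.42, hsa-miR-16 from -1.14 to 0.65, hsa-miR-16-1* from -0.71 to 0.47, hsa-miR-195* from -1.33 to 0.032, hsa-miR-497* from -0.40 to 0.0096 and hsa-mir-503-P from -0.14 to 0.64. The correlation of the variants' changes ran from 0.336 to 0.668. Signal over background limits all of this: 389 of 1773 tested probes exceeded it on all 6 arrays. A lone array of a group was assumed to vary like the other groups. No paired analysis was possible because the replicate numbers follow the order of deposit and pair nothing.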

Other observations

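In this part the fragment list and its tests and the single probes were chosen after values had been seen. For the mouse-named probes and for the count of splits, the bounds were written before those results, the pattern was then widened from miR-195 to all probes above background, and the use of the resampled interval was settled afterwards.

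Most of the listed probes for sequences that overlap transfer RNAs, Y RNAs or vault RNA, entered in older miRNA catalogues, stood higher in both variants than in mock. Of 11 mature-named probes of 10 names, 10 were higher, with a median change of 0.68. They included hsa-miR-1260b (1.65), hsa-miR-1280 (1.08), hsa-miR-1979 (1.06), hsa-miR-1260 (0.86), hsa-miR-1975 (0.68), hsa-miR-1274b (0.68) and hsa-miR-720 (0.49), whereas hsa-miR-886-5p was at -0.29. Camera gave a p of 1.46e-06 at its preset correlation and 0.0809 with an estimated correlation, on a list written after the values were seen, and 0 of the 11 passed over all probes (2 at an unadjusted p under 0.05 in limma). With hsa-miR-1826, an rRNA-related name that the list had left out and whose change was 0.13, the median of 12 probes was 0.67. Whether further names on the array belong on the list was not established, so the counts describe the listed probes alone. The 9 precursor-named probes of these names had a median of 0.37. The median between variants was -0.17.

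A trend with brightness between arrays is argued against: 531 other tested probes within 0.5 log2 units of a fragment probe had a mean change of -0.019 (95% interval -0.05 to 0.02, each fragment probe counting alike), and cyclic loess left the fragment median at 0.71. More small RNA of every abundant class in the labelled RNA of the variant arrays is also argued against, since the 4 small nucleolar RNA probes, also bright, had a mean change of -0.55 with an interval of -1.26 to 0.17, below the fragment median of 0.47 in the lowest fit without 1 array. The real grouping gave the highest median of the 15 splits of the 6 arrays into 4 and 2 (1 of 15, 0.68 against 0.56 in the next), and 15 splits are too few for a share under 0.05. The list was written after the values on this grouping were seen, so neither this rank nor the camera p is evidence for the rise. Total RNA was labelled with random primers, so these probes may also read the whole transfer RNAs, Y RNAs and vault RNA. Fragments cannot be told from these parent RNAs here. A response of any of them to the transfected RNA is a hypothesis that these arrays cannot tell from differences between the arrays.

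Human-named and mouse-named probes of the same mature miRNA gave a check of the changes from mock. Over 82 pairs with both probes above background, of 340 pairs in all, the changes correlated at r = 0.564 (resampled range 0.343 to 0.734, Spearman 0.577), with 45 pairs lower in both probes, 13 higher in both and 24 of opposite sign. Over the other 258 pairs r was 0.115. The value passed the bound of 0.5 by less than its spread, but the range lies above 0.2, so differences private to single probes are unlikely as the whole account of these changes. The resampling treated the pairs as independent, so the range may be too narrow. Differences between arrays unrelated to the transfection stay open: the real grouping had the highest covariance of the 15 splits (1 of 15, 0.0851 against 0.0730 in the next), too few splits for a share under 0.05. The other splits gave r of 0.176 to 0.514, so agreement of the paired probes is not particular to the changes from mock.

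In a limma fit of the 4 variant arrays against the 2 mock arrays, 4.40% of the 1773 probes had an unadjusted p under 0.05. Of the 15 splits of the arrays into 4 and 2, 10, the real one among them, gave as many or more, with 7.05% in the highest other. This count therefore does not set the real grouping apart, and 15 splits cannot give a share under 0.05. After adjustment 0 probes passed in the real split, and 1 other split had any, with 1 probe.

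Among single probes chosen after their values were seen, hsa-miR-663 and hsa-mir-663-P differed from mock by -1.36 and -0.86, in the direction of hsa-miR-663b (-1.84), and hsa-miR-663b-P by 0.08, none past the threshold. The mouse-named probe of miR-21 differed by -1.07 and the 3 mismatch probes of hsa-miR-21 by -0.53, -0.57 and -0.82. The mouse-named probe of miR-195 differed by -0.59 (SE 0.590) and was not above background on all arrays. The mouse-named probe of miR-29b differed by -1.46, and that of miR-20a by -0.38. The 4 small nucleolar RNA probes, U44 and U48, differed by -0.31 to -0.74. In limma over all probes of the table, 0 of those outside the main tests passed in any comparison, with 44 of 1084 mouse-named probes at an unadjusted p under 0.05 for both variants.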
